A study of Micropterus salmoides with 12 samples.

How the data were processed

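Ovarian RNA of 12 female largemouth bass (Micropterus salmoides) was measured on 12 Agilent oligonucleotide arrays of 1 colour (Cy3), with 4 fish from each of 3 sites. Per the labels' protocols, total RNA was extracted with STAT60 and labelled by the Agilent protocol for 1 colour. The labels describe 1 array per fish, so p-values treat each fish as a replicate. Whether the 4 Apopka fish came from 1 mesocosm or from several was not taken into account. Fish sharing a mesocosm would not be independent replicates. Per the file headers, spots were read with Agilent Feature Extraction 10.1.1.1. The deposited scanner tables hold spot intensity on a linear scale (processed signal, mean signal and local background) together with flags for outliers, saturation and signal well above background. The deposited series matrix holds values on a log2 scale. Its ranks followed the scanner signal of the same array, with a Spearman correlation of at least 0.999 on every array, and its column medians lay between 8.83 and 8.91. Its direction is therefore known (higher is more signal), while the normalization behind it is not given in the sources used here.

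Each array carried 15208 probes of 60 bases with 15155 distinct sequences, besides 536 control spots. Control spots were left out of the comparisons, and so were the 232 probe measurements that the scanner software marked as outliers. The written design did not mention outlier marks. Leaving them out follows standard practice for these files, but the counts had been seen both with and without them before that step was settled, and both are given in the closing section. No spot was saturated. The value analysed was log2 of the processed signal minus the 75th percentile of that quantity on the same array. Probes well above background on at least 4 of the 12 arrays, whatever their site, were tested (13474 probes). One model of 3 sites was fitted to all 12 arrays with limma 3.58.1 in R 4.3.3 (lmFit and eBayes), with 9 residual degrees of freedom per complete probe and 3.17 prior degrees of freedom. Each pair of sites was compared as a contrast, and p-values were adjusted by the Benjamini-Hochberg method within a comparison. A probe was called at an adjusted p under 0.05. Fold changes are the first site minus the second on the log2 scale.

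A probe not well above background on any of the 4 arrays of a site has only a bound there. Its fold is then given as "at least", from the brighter site's mean and the dimmer site's mean of, on each array, the higher of the probe's own signal and the lowest signal among probes well above background. For arrays, the number of arrays limits the precision.

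Per the file headers, each site lay on 1 slide of its own (3 slides), and the Apopka slide was scanned on another day than the other slides (2 scan days). Slide, scan day and site therefore cannot be told apart in any comparison with the Apopka mesocosms, and slide and site cannot be told apart between the wild sites. No fit with slide as a block was possible. Sample titles hold the site or mesocosm name for the other sites but the code eOM for the St John River fish. Whether that code marks a further difference from the other fish was not tested.

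The files do not pair the probes with genes. All 15208 descriptions read as unknown, all 15208 coordinates as unmapped, and the names are contig or clone labels, apart from 29 sequence accessions. None of those accessions (0 of 29) was in the gene table of the ASM1485139v1 assembly. The 23 gene lists and the cell type markers fixed before the data were examined could therefore not be matched to any probe, and no list was tested. The rule for named genes asked for probes with a gene name and could not be applied as written. Its numerical criteria were kept: a probe past the threshold, with all 4 arrays of 1 site above all 4 of the other, and well above background on at least 3 of the 4 arrays of the higher site. From each comparison the 2 largest increases and the 2 largest decreases are named by probe ID. The 10 largest in each direction are summarised for Apopka mesocosms against DeLeon Springs. Their range is given only for those well above background on at least 1 array of each site. The labels mark UF_Msa_CF_118449, UF_Msa_AF_100125, UF_Msa_AF_102433, UF_Msa_CF_124566, UF_Msa_AD_200165, UF_Msa_AF_100273 and UF_Msa_AD_200251 as reverse orientation and the other named probes as forward. The strand of the transcripts is not given in the sources used here, so the values are changes of probe signal.

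Alternatives fixed before the data were examined covered the normalization, the background correction (normexp with an offset of 50), the series matrix values, the filter on dim probes, the replicate number as a block, the arrays in the fit, array weights, the prior spread, the threshold and leaving out each array. Keeping the outlier-marked spots, scaling on spike-in probes and adding brightness as a covariate were chosen after seeing the data. The procedure was tested on simulated data with 200 of 13474 probes changed on the Apopka arrays. For Apopka mesocosms against DeLeon Springs it recovered 54% of 50 probes changed 2-fold and 86% of 50 changed 4-fold, with 5 false calls. For Apopka mesocosms against St John River it recovered 42% of 50 changed 2-fold and 88% of 50 changed 4-fold, with 9 false calls. For DeLeon Springs against St John River, where no probe had been changed, it made 0 calls. The simulated noise was independent between probes, with the same spread at all sites and no slide effect. These counts therefore test the procedure and do not give the error rate in the real arrays.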

Results

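The series asked how the ovarian transcriptome of largemouth bass held in mesocosms at Lake Apopka, described by the submitters as carrying high contaminant loads, compared with that of bass from other sites in January. Ovaries of 4 fish from Apopka mesocosms, 4 from DeLeon Springs and 4 from the St John River were profiled. The 75th percentile of the processed signal was 4963 ± 1140 (SD, n = 4) on the Apopka arrays, 2793 ± 913 (SD, n = 4) on the DeLeon Springs arrays and 1313 ± 349 (SD, n = 4) on the St John River arrays. The share of probes well above background was 84.3% ± 2.08 (SD, n = 4), 87.9% ± 1.55 (SD, n = 4) and 84.3% ± 3.31 (SD, n = 4) in the same order. Each site lay on its own slide, so every difference between sites given here is also a difference between slides.

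The arrays grouped by site. The first principal component held 32.3% of the variance and placed the Apopka arrays between 41.4 and 50.6, the DeLeon Springs arrays between -18.9 and -3.64, and the St John River arrays between -46.4 and -19.5. The second held 16.1% and set DeLeon Springs, between -41.3 and -20.1, apart from the other sites, all of whose arrays were above 0. Spearman correlations averaged 0.983 over the 18 pairs of arrays within a site and 0.971 over the 48 pairs between sites. Their ranges overlapped, at 0.971 to 0.991 within and 0.961 to 0.983 between sites. Among pairs of sites the mean was lowest for Apopka mesocosms with St John River, at 0.966 over 16 pairs. DeLeon Springs replicate 4 had the lowest mean correlation with its own site, 0.974. It also lay lowest on the third component (12.3% of variance), at -51.4. The median standard deviation between fish was 0.209 log2 units in the Apopka mesocosms, 0.320 at DeLeon Springs and 0.288 at the St John River. No test was made of these descriptions.

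**Figure D1:**
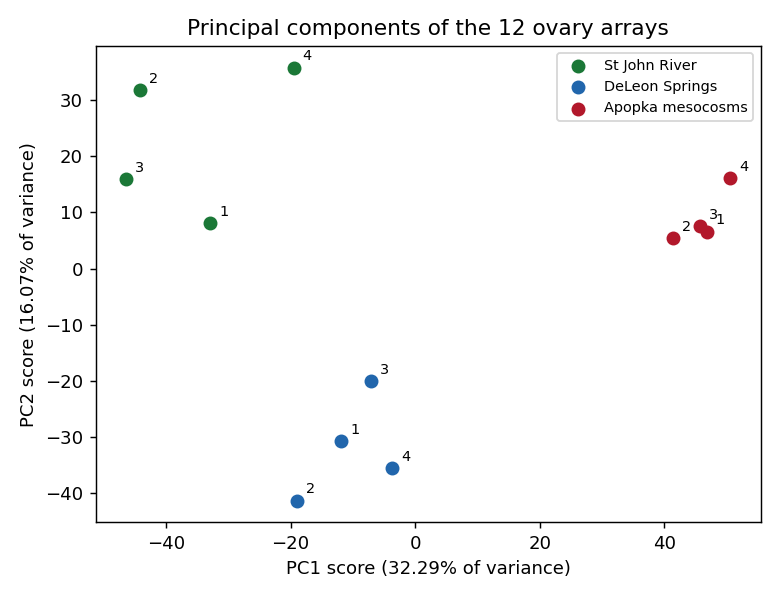
Scores of the 12 ovary arrays on the first principal component (x axis, 32.3% of variance) and the second (y axis, 16.1%), 1 point per fish, coloured by site and numbered by replicate. The 4 Apopka arrays lie above 41 on the first component and the 4 DeLeon Springs arrays below -20 on the second.

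The comparison of Apopka mesocosms with DeLeon Springs asked how mesocosm fish differed from 1 of the wild sites. Of 13474 probes tested, 1493 (11.1%) passed the threshold in limma, 1330 higher and 163 lower in the mesocosm fish. Probe UF_Msa_CF_118449 (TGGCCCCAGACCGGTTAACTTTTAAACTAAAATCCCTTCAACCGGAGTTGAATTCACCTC) was the largest increase under the setting used, with a log2 fold change of 6.85 ± 0.44 (SE) and an adjusted p of 6.82e-06. It was well above background on 4 Apopka arrays but on only 2 of the 4 DeLeon Springs arrays, so the size of the change rests partly on signal near background. Its log2 fold change was 3.88 with normexp and the 75th percentile and 3.70 with normexp and quantile normalization. UF_Msa_CF_126030 (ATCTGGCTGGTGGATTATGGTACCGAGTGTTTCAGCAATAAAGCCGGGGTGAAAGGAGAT) was higher by 5.22 ± 1.27 (SE), with an adjusted p of 0.0195, and lay between -4.47 and 0.39 in the 4 mesocosm fish. UF_Msa_AF_103438 (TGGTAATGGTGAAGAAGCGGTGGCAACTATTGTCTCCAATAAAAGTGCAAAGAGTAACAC) had the largest decrease under the setting used, -3.37 ± 0.77 (SE), with an adjusted p of 0.0139. UF_Msa_AF_100125 (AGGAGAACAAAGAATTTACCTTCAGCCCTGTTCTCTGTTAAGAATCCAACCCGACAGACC) followed at -3.29 ± 0.85 (SE), with an adjusted p of 0.0264. Of the 10 largest increases, 8 were well above background on at least 1 array of each site and ran from 3.65 to 6.85 on the log2 scale. Of the 10 largest decreases, 7 were and ran from -3.37 to -1.71.

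Increases in this comparison were concentrated among dim probes. The tested probes were divided into 4 classes of equal size by mean signal. In the dimmest class 732 of 3369 were higher and 47 lower, against 79 higher and 51 lower of 3369 in the brightest class. The values of 2594 probes (19.2%) did not overlap between the 4 fish of each site, where chance gives 2.86%. The split between directions depended on the scaling: 837 probes were higher and 455 lower with quantile normalization, 984 and 485 with the median as the scaling point, 860 and 389 with the series matrix values, and 693 and 267 with normexp and quantile normalization. The count was 612 with normexp and the 75th percentile, 2367 with no filter on dim probes and 2264 with array weights. The log2 fold change of UF_Msa_CF_126030 was 3.44 and 3.23 with normexp and the 75th percentile and with normexp and quantile normalization, 6.09 without Apopka mesocosms replicate 1, 5.82 without DeLeon Springs replicate 4 and 4.47 without Apopka mesocosms replicate 2. Its call was lost without DeLeon Springs replicate 1 (adjusted p 0.0546) or 3 (0.0528), and without Apopka mesocosms replicate 2 (0.0574) or 3 (0.0523). The call of UF_Msa_AF_100125 was lost without DeLeon Springs replicate 1 (0.0772) or 4 (0.0559), without Apopka mesocosms replicate 3 (0.0786), and with only the 2 groups compared in the fit (0.0508). Without Apopka mesocosms replicate 2 its log2 fold change was -2.44 and that of UF_Msa_AF_103438 was -2.49, and without Apopka mesocosms replicate 1 that of UF_Msa_AF_100125 was -3.88.

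**Figure D2:**
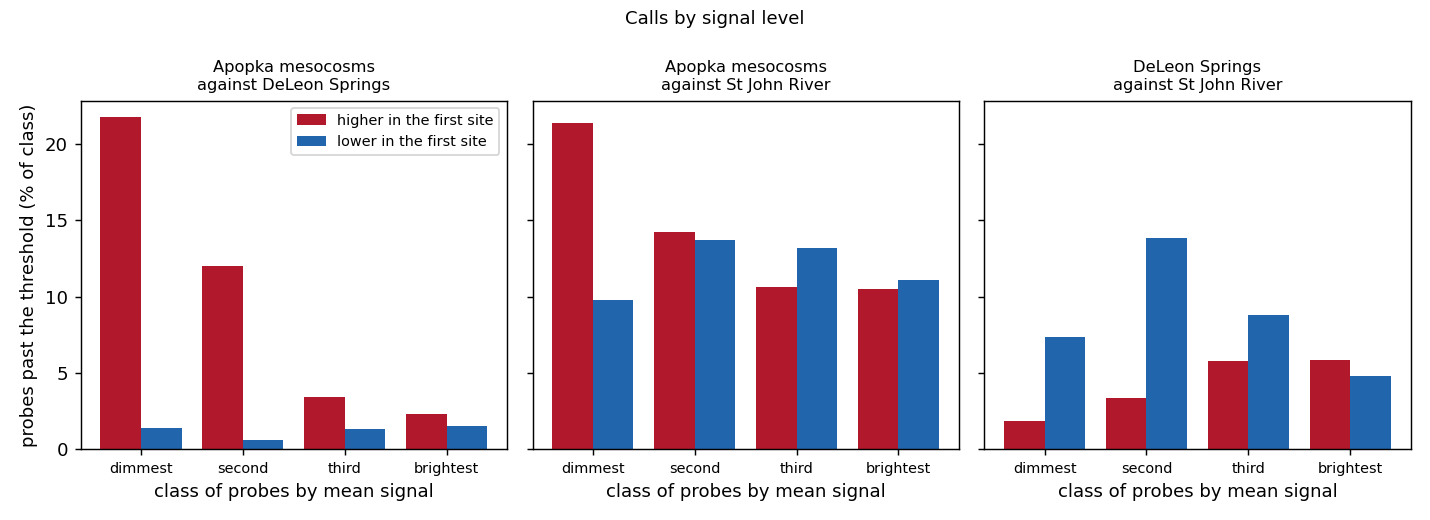
Percent of probes past the threshold (y axis) in each of 4 classes of the tested probes by mean signal (x axis), for the 3 comparisons, with bars for probes higher and lower in the first site. In Apopka mesocosms against DeLeon Springs, 21.7% of the dimmest class was higher and 1.40% lower, against 2.34% and 1.51% of the brightest class. The split between directions depends on the scaling: with quantile normalization 64.8% of the calls in this comparison were higher, against 89.1% here.

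The comparison of Apopka mesocosms with the St John River gave the most calls of the 3 under the scaling used. Of 13474 probes, 3517 (26.1%) passed, 1910 higher and 1607 lower in the mesocosm fish. UF_Msa_AF_102433 (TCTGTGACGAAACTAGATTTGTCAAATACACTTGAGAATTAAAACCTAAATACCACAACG) was higher by 6.44 ± 0.53 (SE) on the log2 scale, with an adjusted p of 4.56e-05. It was well above background on 4 Apopka arrays but on only 1 of the 4 St John River arrays, so the size of the change rests largely on signal not above background. Its log2 fold change was 2.76 with normexp and the 75th percentile and 3.45 with normexp and quantile normalization. UF_Msa_CF_118449, the largest increase against DeLeon Springs, was higher here by 6.41 ± 0.44 (SE), with an adjusted p of 1.48e-05. It too was well above background on 1 of the 4 St John River arrays, and the same alternatives gave 2.92 and 3.65. UF_Msa_CF_124566 (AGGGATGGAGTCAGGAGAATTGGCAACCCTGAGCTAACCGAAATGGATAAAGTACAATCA) was not well above background on any Apopka array and was at least 25.1-fold lower there, with an adjusted p of 0.032. The St John River fish differed widely in it, at -5.47, 0.05, 0.35 and -4.99 for replicates 1 to 4, and the bound became at least 49.6-fold, 13.9-fold, 12.9-fold and 44.4-fold lower without each of them in turn. UF_Msa_AD_200165 (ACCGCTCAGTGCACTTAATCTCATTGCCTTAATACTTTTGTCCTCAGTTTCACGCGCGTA) was lower by a log2 fold change of -3.37 ± 0.86 (SE), with an adjusted p of 0.0137. That value was -2.57 and -2.04 with the same alternatives and -4.00 without Apopka mesocosms replicate 4.

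In the dimmest class of probes 720 of 3369 were higher and 329 lower in the mesocosm fish, and in the brightest class 354 were higher and 374 lower. The values of 4256 probes (31.6%) did not overlap between the sites, where chance gives 2.86%. With normexp and the 75th percentile the split became 1096 higher and 4658 lower, and with spike-in scaling, which was chosen after seeing the data and moved the median log2 fold change of all probes by 1.52, 11574 higher and 13 lower. The call of UF_Msa_CF_124566 was lost without St John River replicate 2 (adjusted p 0.088) or 3 (0.0907), and without Apopka mesocosms replicate 1 (0.0721), 2 (0.0642), 3 (0.0618) or 4 (0.058). It was also lost with normexp and quantile normalization (adjusted p 0.0848) and with trend and robust options in eBayes (0.0547).

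The comparison of DeLeon Springs with the St John River set the wild sites against each other. Of 13474 probes, 1740 (12.9%) passed, 568 higher and 1172 lower at DeLeon Springs. UF_Msa_AF_100273 (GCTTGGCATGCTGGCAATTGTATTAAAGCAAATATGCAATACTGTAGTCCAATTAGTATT) was higher by 3.24 ± 0.67 (SE), with an adjusted p of 0.0117, and was well above background on 1 of the 4 St John River arrays. With normexp and the 75th percentile its log2 fold change was 0.16 and its adjusted p 0.763, and with normexp and quantile normalization it was 1.13. UF_Msa_AF_106627 (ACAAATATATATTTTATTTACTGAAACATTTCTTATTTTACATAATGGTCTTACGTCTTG) was higher by 2.61 ± 0.30 (SE), with an adjusted p of 0.00223, and by 0.59 (adjusted p 0.0413) and 1.34 with the same alternatives. UF_Msa_AF_109020 (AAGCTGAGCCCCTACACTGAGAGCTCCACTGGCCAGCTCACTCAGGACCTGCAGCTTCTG) had a log2 fold change of -3.93 ± 0.75 (SE), with an adjusted p of 0.00849, and -2.86 and -2.56 with these alternatives. UF_Msa_AD_200251 (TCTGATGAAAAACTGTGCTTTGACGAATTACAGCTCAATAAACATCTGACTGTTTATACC) had one of -3.34 ± 0.90 (SE), with an adjusted p of 0.0319, and -1.50 and -0.999 with these alternatives. It was not well above background on 2 of the 4 DeLeon Springs arrays.

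The majority direction between the wild sites turned with the scaling: 959 probes were higher and 652 lower with the median as the scaling point, 680 and 722 with quantile normalization, 734 and 723 with the series matrix values, 666 and 739 with normexp and quantile normalization, 712 and 4722 with normexp and the 75th percentile, and 4928 and 12 with spike-in scaling. The count fell to 626 when only these sites were fitted, to 883 without St John River replicate 2, to 962 without St John River replicate 4 and to 973 without DeLeon Springs replicate 1. Fits of only the 2 groups compared gave 1622 for Apopka mesocosms against DeLeon Springs and 3839 against the St John River. The main fit shares 1 spread with the mesocosm fish, whose median standard deviation, 0.209, was the lowest. Whether that sharing accounts for the larger count in the main setting was not tested. The call of UF_Msa_AD_200251 was lost without any 1 of the 4 St John River arrays (adjusted p 0.064, 0.0598, 0.0524 and 0.0702 for replicates 1 to 4), without DeLeon Springs replicate 2 (0.0691) or 3 (0.0518), with only the 2 groups compared in the fit (0.0694) and with array weights (0.073). Its log2 fold change was -2.43 without DeLeon Springs replicate 3 and -4.21 without DeLeon Springs replicate 1.

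**Figure D3:**
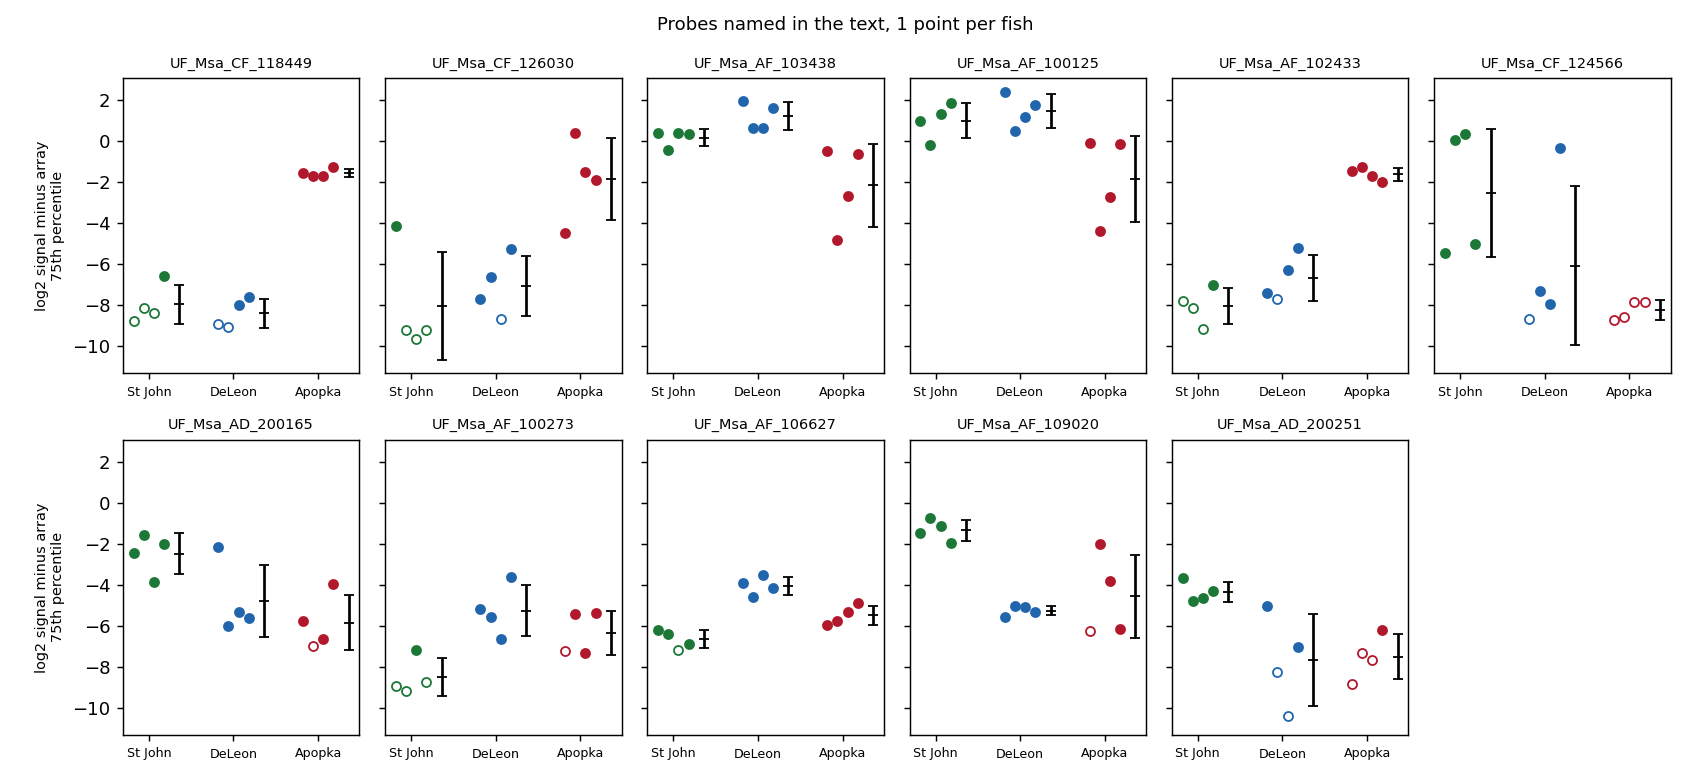
Log2 signal minus the array's 75th percentile (y axis) of each probe named in the text, by site (x axis), 1 point per fish, with filled points for spots well above background and open points for the others. Black marks give the mean and SD of the 4 fish. UF_Msa_CF_118449 has a mean of -1.55 in the Apopka mesocosms, -8.40 at DeLeon Springs and -7.96 at the St John River.

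Probes that differed the same way in the mesocosm fish against both wild sites numbered 1061, of which 949 were higher and 112 lower, and 9 went opposite ways. Both comparisons share the mesocosm arrays. Unchanged groups simulated with the same sharing gave 0 such probes on average and at most 0 in 100 draws, and independent lists of these sizes would share 188.5 higher and 19.4 lower. No group differed in that simulation, so its counts do not show what sharing adds when many probes are called. The figures for independent lists leave the sharing out. With the mesocosm arrays divided so that each comparison used 2 of them, the 6 divisions gave 263 to 332 probes changed the same way and 0 to 2 changed opposite ways, from 607 to 775 calls against DeLeon Springs and 787 to 1776 against the St John River. This division removes the shared arrays but not the shared slide of the mesocosm fish. Across probes, which are not independent replicates, the fold changes of these comparisons had a Pearson r of 0.696, against 0.499 in the simulation. Their covariance was 0.297 against a simulated 0.0504. The split of these probes was 710 higher and 318 lower with quantile normalization, 811 higher and 257 lower with the median as the scaling point, 727 higher and 265 lower with the series matrix values, 600 higher and 157 lower with normexp and quantile normalization, 302 higher and 88 lower with normexp and the 75th percentile, and 1396 higher and 1 lower with spike-in scaling.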

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

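The quantile normalization in this part was fixed before the data were examined and the splits for the probes shared by both mesocosm comparisons before their result was seen, while the bound set on the quantile share and the other tests of explanations were chosen after the results they bear on had been seen.

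Of 63 groups of 4 values examined, 3 held a fish far from the other fish of its site, about what chance gives at 1 in 20. UF_Msa_CF_126030 was at -4.11 in St John River replicate 1 and between -9.65 and -9.20 in the other fish of that site. UF_Msa_AF_103438 was at -0.423 in St John River replicate 2 and between 0.361 and 0.406 in the others. UF_Msa_CF_124566 was at -0.301 in DeLeon Springs replicate 4 and between -8.67 and -7.33 in the others. Among 47 kinds of control spot that the comparisons do not use, 3 kinds were brighter on all 4 Apopka arrays than on any wild-site array relative to the 75th percentile, and 2 of them were not well above background on any array. The 1 kind that was well above background on 3 of the 4 Apopka arrays (DCP_20_9) measured 2.22 log2 units higher there on average, but it was well above background on 1 of the 8 wild-site arrays, so the size of that difference is not settled. Of the 15 kinds well above background on all 12 arrays, 14 averaged lower on the Apopka arrays than on the wild-site arrays. Their differences ran from -1.50 to -0.44 log2 units. The other, DCP_20_7, averaged higher, by 0.732. Among the DCP_20 kinds the difference changed sign as their level on the wild-site arrays fell. It was -1.50 for DCP_20_0, -1.435 for DCP_20_1, -1.27 for DCP_20_3, -1.20 for DCP_20_5, 0.732 for DCP_20_7 and 2.22 for DCP_20_9. The DCP_1 and DCP_22 kinds among the 15 all averaged lower.

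Chance assignment of arrays to sites is argued against for the 3 counts but not excluded, since 35 splits allow no small p-value. In each, 1 of the 35 splits of the 8 arrays, the real one, gave as many probes. The real counts were 1493, 3517 and 1740 for Apopka mesocosms against DeLeon Springs, Apopka mesocosms against St John River and DeLeon Springs against St John River, and the highest other split gave 2, 1 and 2 probes. For the 1061 probes changed the same way against both wild sites, 1 of 100 drawn splits gave as many, again the real one. The highest other gave 902, and it was the 1 drawn split that kept the 4 Apopka arrays together, while the highest with them apart gave 2. These splits say nothing of slide against site, since no slide held fish of more than 1 site.

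In Apopka mesocosms against DeLeon Springs, 89.1% of the calls were higher, most of them on dim probes. The low end of the signal was raised on the Apopka slide relative to the 75th percentile. All 28 kinds of control spot that were not well above background on any array averaged higher there than at DeLeon Springs, by a median of 1.205 log2 units, and 27 of 28 higher than at the St John River, by 0.423. The detection floor lay between -7.47 and -6.89 on the Apopka arrays, -8.61 and -7.85 on the DeLeon Springs arrays and -7.91 and -6.91 on the St John River arrays. Probes near background on average do not account for the excess alone: among 10216 probes with a mean signal at least 8 times the detection floor, 84.3% of calls were higher, and 80.0% to 91.1% without each array in turn. That mean was over all 12 arrays, so a probe near background at 1 site could be included. The excess shrank with brightness, from 404 higher and 21 lower in the second dimmest class to 115 and 44 in the third. In the brightest class it was 79 and 51. The test by detection floor leaves the raised low end open for the dimmer probes and for probes dim at 1 site. The share changed with the scaling, and none of those tried made it even: it was 64.8% with quantile normalization (63.4% to 73.6% without each array), where lower calls rose from 163 to 455, 67% with the median, 68.9% with the series matrix values, 72.2% with normexp and quantile normalization, 81.9% with normexp and the 75th percentile, 90% with the 75th percentile of probes well above background on all 12 arrays and 98.7% with spike-in scaling. A flatter response on the Apopka slide over the range of the spike-in probes as a set is argued against by their slope. It was 0.104 steeper there on average and steeper on each Apopka array than on any DeLeon Springs array. A single slope does not test flattening among dim signals alone. The raised undetected control spots and the change of sign among the DCP_20 kinds leave such flattening open. What also stays open is any other effect of slide or scan day and a difference between the fish of the sites, which cannot be told apart because each site lay on its own slide.

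Deviations of the arrays from their site means had a main axis that held 23.1% of the variance within sites. DeLeon Springs replicates 4 and 2 lay farthest out on it, at -0.624 and 0.476, so much of it rests on these arrays. Overall brightness may contribute to it: the axis and the 75th percentile, both centred within site, had a Pearson r of 0.655 (permutation p = 0.0519 over 13824 permutations within site) and a Spearman rho of 0.51 (permutation p = 0.163) over 12 arrays. Without 2 arrays r was 0.625 (permutation p = 0.109) when those farthest from the median brightness were left out, and 0.308 (permutation p = 0.397) when those farthest from the median of centred brightness were. Whether brightness is the source is undecided: a first bound, a permutation p of 0.05 or more, would have excluded it, and was replaced by 0.5 after the p of 0.0519 had been seen, since a p that narrowly misses a threshold excludes nothing. The labels give no property of single fish, so no biological explanation was tested.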

How the results depend on the processing

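Spike-in scaling, brightness as a covariate and keeping outlier-marked spots were chosen after seeing the data. Counts are in the order Apopka mesocosms against DeLeon Springs, Apopka mesocosms against St John River, DeLeon Springs against St John River, and probes changed the same way in the mesocosms against both wild sites, with 1493, 3517, 1740 and 1061 in the main setting. With outlier-marked spots kept the first 3 were 1517, 3486 and 1740. The counts that moved by over 1.5 times were 612, 5754, 5434 and 390 with normexp and the 75th percentile; 960 for the first with normexp and quantile normalization; 2367 for the first with no filter; 2264 for the first with arrayWeights; 626 for the third with only the 2 groups compared; 752, 1666, 396 and 554 at an adjusted p under 0.01; and 902, 1408, 481 and 631 with at least 2-fold also asked, where the stricter threshold is itself the cause. With spike-in scaling 11587 and 4940 probes passed in Apopka mesocosms against St John River and DeLeon Springs against St John River, 11574 and 4928 of them higher, since this scaling moved the median log2 fold change of all probes by 1.52 and 1.03 (0.485 in the first, with 1403 of 1421 higher). The cause of the other moves was not tested. Leaving out each array in turn gave 1066 to 1572, 2435 to 4027, 883 to 1843 and 789 to 1144. The third count was 883 without St John River replicate 2, 962 without St John River replicate 4 and 973 without DeLeon Springs replicate 1.

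Whether the replicate numbers pair the fish is not settled. Correlations of deviations in the 12 same-numbered pairs ran from -0.249 to 0.271, with 3 over 0.1. In turn, 7 of 12 arrays correlated best with an array of their own number, and no chance level was computed for either count. With the replicate block the counts were 1364, 3256, 1387 and 1002. The mean within-site minus between-site Spearman correlation, 0.0119, stayed between 0.0092 and 0.0138. Of 314 values of the named probes under alternatives, 289 stayed past the threshold, 25 did not and 0 reversed. The named probes were chosen for not overlapping between sites in the main setting, so leaving out an array could not reverse them. All 12 named values passed in the main setting, as their choice required, and 2 with the filter to probes well above background on all 12 arrays, which left the others untested. Slide as a block was not possible, and the gene list alternatives were not run because no probe has a gene name. Signal over background limits the dim probes: the lowest signal counted as well above background lay at -8.61 to -6.89 log2 units relative to the 75th percentile.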

Other observations

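The tests in this part were chosen after the data had been seen. The array carried 197 targets as a pair of probes in opposite orientations, and 104 pairs had both probes tested. A further 33 targets had only the forward probe tested and 34 only the reverse probe. UF_Msa_AD_200165 and UF_Msa_AD_200251 are reverse probes of such targets, and the values of their forward partners are not given here. In Apopka mesocosms against DeLeon Springs, 22 forward and 27 reverse probes among all of these were higher, and 1 forward and 0 reverse were lower. Together 49 of the 275 tested probes of these targets were higher, against 1330 of all 13474 probes tested. Of the 104 pairs, 2 were higher with both probes, 0 lower with both and 0 opposite. The same counts were 4, 3 and 7 in Apopka mesocosms against St John River and 0, 0 and 3 in DeLeon Springs against St John River. Across the 104 pairs, which are not independent replicates, the Pearson r of the fold changes was 0.237 in that comparison, -0.134 in Apopka mesocosms against St John River and -0.072 in DeLeon Springs against St John River. Probes of identical sequence gave closer values: over 40 pairs, r was 0.91, 0.898 and 0.905 in the same order, and the median difference between such probes on 1 array was 0.127 log2 units.

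Spike-in probes relative to the array's 75th percentile averaged 0.625 ± 0.302 log2 units (SD, n = 4) in the Apopka mesocosms, 1.11 ± 0.62 (SD, n = 4) at DeLeon Springs and 2.15 ± 0.58 (SD, n = 4) at the St John River. The difference between Apopka mesocosms and St John River was -1.52, with an exact 2-sided permutation p of 0.0286, the smallest this design can give, and 0.0856 after adjustment over 3 comparisons. Apopka mesocosms against DeLeon Springs differed by -0.486 (exact permutation p = 0.257) and DeLeon Springs against St John River by -1.03 (exact permutation p = 0.0571).

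Both mesocosm fish and DeLeon Springs fish differed the same way from St John River fish on 1101 probes, 386 higher and 715 lower, with 14 opposite. These comparisons share the St John River arrays. Simulated unchanged groups gave 0 such probes, and independent lists would share 80.5 higher and 139.8 lower. Neither figure shows what the shared arrays add when many probes are called. The direction of the split depended on the scaling: 441 higher and 549 lower with quantile normalization, 502 and 453 with the median as the scaling point, 394 and 3528 with normexp and the 75th percentile, and 4840 and 6 with spike-in scaling. The count of 1101 fell to 573 without St John River replicate 2, 680 without St John River replicate 4 and 683 without DeLeon Springs replicate 1. It was 497 with only the 2 groups compared in each fit. With the St John River arrays divided 2 and 2, DeLeon Springs had 1 to 3 calls, 0 to 1 probes differed the same way in both comparisons, and the Pearson r of fold changes across probes lay between 0.272 and 0.521.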
